A study of Camponotus fellah with 299 samples.

How the data were processed

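Brains of 299 ants of the carpenter ant species Camponotus fellah were sequenced singly, 90 from colony 2, 104 from colony 3 and 105 from colony 4. Per the labels' protocols, RNA was extracted with Tri reagent and stranded mRNA libraries were made with a KAPA kit. The deposited values are whole read counts per gene model, not normalized, in a table of 14664 gene models. Per the submitters' processing notes, STAR and featureCounts were used to make the counts; their versions, the genome build, the annotation and the strand setting were not given in the sources used here. Without the strand setting, reads of overlapping gene models on opposite strands, and reads shared by near-identical copies, could not be assigned with certainty. The identifiers have the form evm.model, contig and number, and name 938 contigs; the files do not pair them with gene names, and no reference was used here.

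The library totals ran from 19.8 to 73.2 M counted reads (M, 1e+06 reads), with a median of 38.3 M, and the gene with the most reads took 1.56% of all counts. No library fell under the minimum of 1 M reads, and 675 gene models had no read in any ant. The highest correlation of log2 CPM (counts per M counted reads) between any pair of ants was 0.990, against a median over ants of 0.986 for the nearest other ant, and no library stood out as a repeat of another. At this depth 10457 gene models passed edgeR's filterByExpr on the colony groups, with its minimum count of 10, and held 99.99% of the counts.

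The labels give each ant's colony, age in months, body length, head width, tallies of behaviours seen in the nest and on the foraging side, a maturity value from 0 to 1 and a nurse-forage ratio. They define neither maturity nor the ratio. Maturity was read as the social network position that the title of the series refers to, and the ratio as rising with foraging. In 10 ants, 3 of colony 2, 6 of colony 3 and 1 of colony 4, these labels were missing, so 289 ants were tested. In colony 4 the deposited maturity rose with brood care and fell with age, the opposite of colonies 2 and 3. Oriented maturity is therefore 1 minus the deposited value in colony 4 and the deposited value in the other colonies. This orientation was set from the labels, before any expression value was examined. The tests, the rule for named genes and most of the alternatives were also fixed before that.

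Each main test was an edgeR (4.0.16) quasi-likelihood F-test with robust dispersion estimates, TMM normalization and Benjamini-Hochberg adjustment over all genes tested, with an adjusted p below 0.05 taken as called. All 289 ants entered each main model, so that the 3 colonies shared an estimate of the spread, with colony as a covariate. The fits of colonies 2, 3 and 4 alone held 87, 98 and 104 ants, each with its own estimate of the spread. The slope of maturity is the log2 change from 0 to 1, and that of age is per 12 months. The nurse-forage ratio was used as deposited and each tally as log2 of the tally plus 1. Standard errors were taken from the slope and its F statistic. Age, foraging and brood care were each tested alone and with maturity in the model. Low and high ends of oriented maturity were set at below 0.25 and above 0.75, for description and for tests of correlations inside the ends and between them. Two-sided permutation tests of single correlations used 100000 resamples.

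Maturity, age, foraging and brood care were also predicted by ridge regression on log2 CPM (prior count 1) centred within colony, with a penalty equal to the number of genes and 10-fold cross-validation. The R-squared was taken against the colony mean, and 99 permutations of the outcome within colony gave its p. Errors per ant were compared by a two-sided permutation test that flipped the signs of the differences 100000 times. These steps ran in Python 3.11.15 with numpy 2.4.6, the others in R 4.3.3.

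The rule for named genes took the largest absolute slopes on maturity among called genes with a mean log2 CPM of at least 2, taken as the average log2 CPM that edgeR reports, and the same sign of slope in each colony fitted alone. That average follows the mean abundance, so single ants can raise it. It was 2.65 for evm.model.ctg8.121 and 2.09 for evm.model.ctg53.29, and 0.52 and 1.91 without the ant with the highest value, below the bound. The means of the log2 CPM of single ants (prior count 1) were 0.26 and -2.31, so neither would be named by that reading. Because the identifiers carry no names, 2 that rose and 2 that fell were taken, and these were followed through the other models. The gene lists fixed in advance (hormone, neuropeptide, chemosensory, immune, metabolic and cell type lists) could not be matched to identifiers, so no gene list was tested.

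The models were tested on simulated counts for 10457 genes, of which 67, 67 and 66 were changed by 3 sizes of slope. For maturity alone, 82.1% of simulated changes of 0.25 log2, and 100% of those of 0.5 and 1 log2, were recovered, and 6.47% of the 201 calls were false. For maturity given age, 71.6% of changes of 0.25 log2 and 85.1% of those of 0.5 were recovered. The simulated genes varied independently, and their expression did not follow depth or runs of ants, so these rates may not hold for the real counts. For age given maturity, 50.7% of changes of 0.1 log2 per 12 months and 91.0% of those of 0.25 were recovered. The ridge regression recovered an R-squared of 0.455 for an outcome made of 3 components of expression and noise of equal variance.

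The alternatives were DESeq2's size factors (RLE) in place of TMM, no filter on low counts, DESeq2 (1.42.0), limma-voom (limma 3.58.1), each colony left out, other scales of age and maturity, maturity as deposited, added covariates, log2 library size, and 3 principal components of the residuals of the model without the tested terms. For a joint model both terms were left out, and such components can hold the tested signal. Chosen after seeing the data were 3 components of the residuals of the full model, age with its own slope in each colony, library size in the body length model, runs of 10 ants with consecutive numbers in a colony as blocks in place of colony, named genes without the ant with the highest value, and the counts without the ant highest in evm.model.ctg8.121. The share of variance between runs was tested by permuting the ants of a colony 100000 times, one-sided. Other splits of the ants were drawn 100 times, the real one included, permuting residuals within colony, or ants between 2 colonies for the colony comparisons, and testing with limma.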

Results

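Gene expression was measured in the brains of 299 ants of Camponotus fellah, a carpenter ant, by RNA-seq of single brains. The colonies had been followed for a week, with the behaviour of the ants recorded, before the ants were killed. The series asks how the position of a worker in the social network of its colony relates to brain expression. Median library totals were 41.2 M counted reads in colony 2, 38.4 M in colony 3 and 37.2 M in colony 4 (M, 1e+06 reads). The tests used the 289 ants with age, maturity and behaviour labels. Of these ants, 38, 55 and 69 of colonies 2, 3 and 4 stood at the low end of oriented maturity, 39, 24 and 24 at the high end, and 10, 19 and 11 between. The p-values measure the spread between ants of these 3 colonies, and the labels give no sequencing batch.

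Maturity, the label read here as social network position, ran from ants that mostly tended brood to ants that rarely did, many of which foraged. Ants at the low end of oriented maturity were younger on average, with a mean age of 9.99 ± 6.80 months (SD, n = 162). Most of them tended brood, with a mean brood care tally of 12.2 ± 12.6 (SD). The median tally at this end was 10.5, 12 and 4 in colonies 2, 3 and 4. Some low-end ants had a tally of 0, and some were old, such as an ant of colony 3 aged 38 months. Ants at the high end had a mean age of 25.0 ± 9.59 months (SD, n = 87) and a brood care tally of 0.126 ± 0.367 (SD). The mean nurse-forage ratio was 0.00127 ± 0.00903 (SD) at the low end and 0.521 ± 0.376 (SD) at the high end. At the high end of colonies 2, 3 and 4 it was 0.307 ± 0.337, 0.619 ± 0.347 and 0.771 ± 0.259 (SD), with a ratio of 0 in 10 of 39, 4 of 24 and 0 of 24 ants, and the mean guarding tally was 4.69 ± 6.97, 2.63 ± 3.87 and 2.25 ± 4.98 (SD). The remaining 40 ants lay between the ends, so most ants stood near 0 or 1.

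In the deposited values, maturity rose with age in colonies 2 and 3 and fell with age in colony 4. Pearson's r between deposited maturity and age was 0.735 in colony 2 (n = 87), 0.776 in colony 3 (n = 98) and -0.671 in colony 4 (the remaining ants of the 289), with Spearman's rho of 0.725, 0.786 and -0.708. Deposited maturity fell with brood care in colonies 2 and 3, with rho of -0.864 and -0.833, and rose with it in colony 4, with rho of 0.83; Pearson's r was -0.638, -0.604 and 0.459. For the nurse-forage ratio rho was 0.748, 0.678 and -0.71, and r was 0.565, 0.785 and -0.895. Each of the 9 relations had a permutation p of 1e-05 for both r and rho, the smallest that 100000 resamples can give, and an adjusted p of 1e-05. Without the 2 ants farthest from the median maturity, r with age was 0.729, 0.766 and -0.646, r with brood care was -0.637, -0.599 and 0.453, and r with the ratio was 0.562, 0.769 and -0.889. Because the ants gathered at both ends, age was also compared with oriented maturity inside each end, in 6 relations. At the low end rho was 0.48, 0.52 and 0.48 in colonies 2, 3 and 4 (adjusted permutation p of 0.0054, 0.00018 and 0.00012), and r was 0.55, 0.35 and 0.45 (adjusted permutation p of 0.0014, 0.022 and 9e-04). Without the 2 farthest ants, r at the low end was 0.59, 0.46 and 0.41. At the high end rho was 0.09, -0.17 and 0.4 and r was 0.15, -0.13 and 0.14, with no adjusted permutation p below 0.078. All tests below use the orientation in which maturity rises with age and foraging in each colony.

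**Figure D1:**
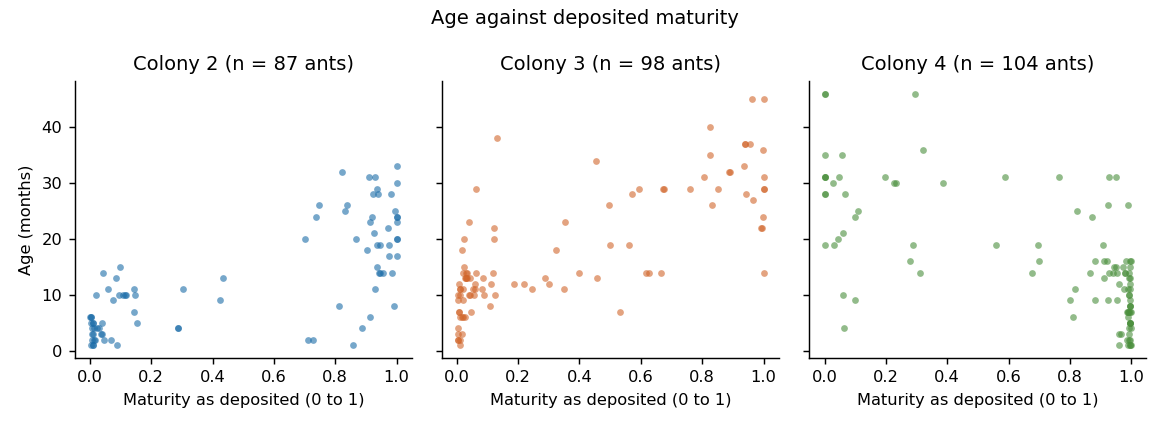
Age in months against maturity as deposited, from 0 to 1, for the 289 labelled ants, in a panel for each colony and with a point for each ant. Older ants stand at high deposited maturity in colonies 2 and 3 (rho of 0.725 and 0.786) and at low deposited maturity in colony 4 (rho of -0.708).

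Brain expression changed along maturity in a large part of the genes, in both directions and mostly by small amounts. Of 10457 genes tested, 4770 were called in the model with colony, 2446 rising and 2324 falling from low to high maturity. The median absolute slope of the called genes was 0.141 log2, and 166 of them changed by more than 1 log2, 78 rising and 88 falling. Maturity took 4.26% of the variance of expression within colonies, where a term unrelated to expression would take about 0.35%. With maturity as deposited in all 3 colonies 553 genes were called. With 3 residual components of the model without maturity added, 3819 genes were called, of which 1917 were among the 4770 (40.2% of these).

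The gene model evm.model.ctg89.12 rose with maturity in each colony. Its mean was 12.6 ± 9.54 CPM (SD, n = 162) at the low end and 41.9 ± 13.7 CPM (SD, n = 87) at the high end, a slope of 2.23 ± 0.12 log2 (SE; edgeR adjusted p = 8.11e-49). Fitted alone, colonies 2, 3 and 4 gave slopes of 2.06 ± 0.18, 2.77 ± 0.19 and 1.89 ± 0.22 log2 (SE). The gene model evm.model.ctg53.29 was found mostly in low-maturity ants. Its mean was 7.50 ± 17.2 CPM (SD) at the low end, where 37 of 162 ants had no read of it, and 0.0291 ± 0.0625 CPM (SD) at the high end, where 61 of 87 ants had none. Its slope was -10.93 ± 0.59 log2 (SE; edgeR adjusted p = 1.84e-48), and the levels at the low end were skewed, with a median of 0.588 and a highest value of 147.7 CPM.

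The gene model evm.model.ctg75.11 fell with maturity, from 72.3 ± 226 CPM (SD, median 22.9) at the low end to 9.88 ± 27.2 CPM (SD, median 4.46) at the high end. Its slope was -3.55 ± 0.30 log2 (SE; edgeR adjusted p = 2.69e-24), and -3.32 ± 0.28 without the colony 4 ant at 2523 CPM. The rise of evm.model.ctg8.121 rested largely on 1 ant of colony 3, at 1417 CPM. Its medians were 1.08 CPM at the low end and 1.41 CPM at the high end, the means being 1.10 ± 0.53 and 18.0 ± 152 CPM (SD). The slope was 2.89 ± 0.31 log2 (SE; edgeR adjusted p = 7.3e-17) and 0.60 ± 0.12 without that ant (edgeR adjusted p = 7.41e-06). It met the abundance bound for named genes through that ant, with an average log2 CPM of 2.65 and of 0.52 without it, and evm.model.ctg53.29 met it through the ant at 147.7 CPM, with 2.09 and 1.91. The files do not pair these identifiers with gene names.

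**Figure D2:**
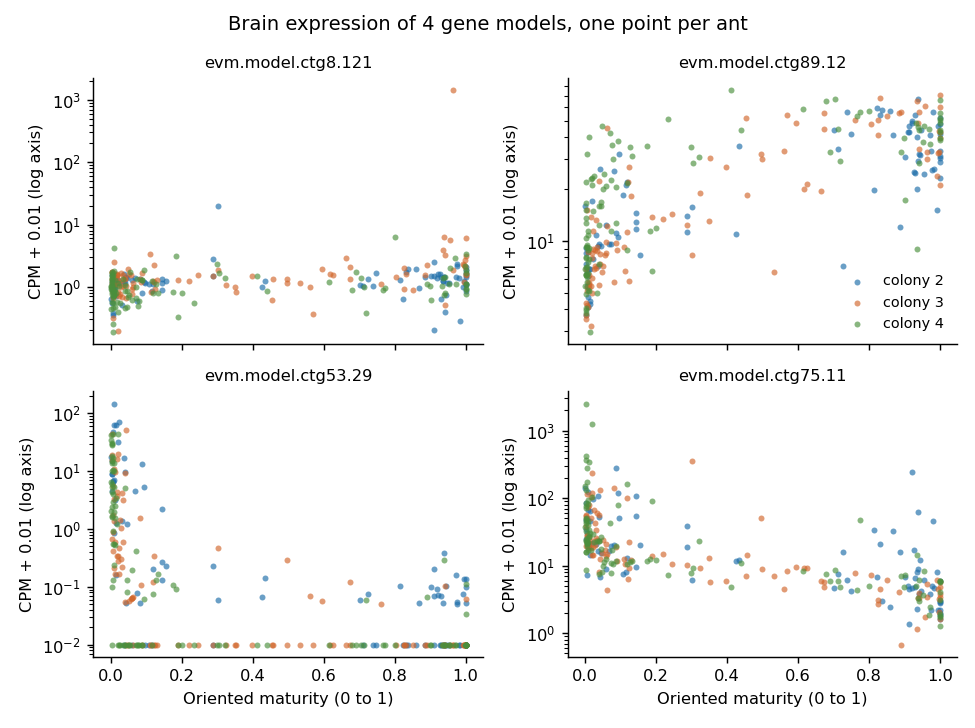
Expression of the 4 gene models against oriented maturity (0 to 1), as CPM plus 0.01 on a log axis, with a point for each of 289 ants coloured by colony. The rise of evm.model.ctg89.12 is spread over the ants, with medians of 9.07 CPM at the low end and 43.1 CPM at the high end, evm.model.ctg53.29 lies at 0 reads in 61 of 87 high-maturity ants, and a single ant at 1417 CPM stands above the others in evm.model.ctg8.121.

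The slopes on maturity were alike in part between colonies, and most alike between colonies 2 and 4. Fitted alone, colonies 2, 3 and 4 called 2600, 2826 and 3518 genes. Colonies 2 and 4 had 1744 called genes in common, where independent lists would share 874.7, and 1738 of them had the same sign of slope. Colonies 2 and 3 shared 1166 genes (702.6 for independent lists), 1055 of the same sign, and colonies 3 and 4 shared 1473 (950.7), 1378 of the same sign. Across the 10457 genes, which are not independent replicates, Spearman's rho of the slopes was 0.665 between colonies 2 and 4, 0.368 between 2 and 3 and 0.467 between 3 and 4. In all 3 colonies 873 genes were called with one sign, 467 rising and 406 falling.

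Slopes that differed between colonies were found in 1696 genes by the F-test of the interaction of maturity and colony. Among these, 166 were called with opposite signs in different colonies, and 539 had the same sign in all 3. The median spread between the highest and lowest slope was 0.263 log2 in these genes. The interaction was called for evm.model.ctg75.11 (edgeR adjusted p = 0.000222, and 0.0018 without the colony 4 ant at 2523 CPM), whose slopes in colonies 2, 3 and 4 were -1.98 ± 0.42, -3.88 ± 0.42 and -4.99 ± 0.58 log2 (SE). Its medians in these colonies fell alike, from 23, 21.7 and 24.2 CPM at the low end to 4.78, 3.62 and 4.59 CPM at the high end. A high-end ant of colony 2 stood at 242.2 CPM, the next at 62.71 CPM, and no fit left that ant out. For evm.model.ctg8.121 the interaction rested largely on the colony 3 ant at 1417 CPM. The slopes of this gene model were 0.07 ± 0.25, 6.05 ± 0.50 and 0.63 ± 0.19 log2 (SE) and the interaction had an edgeR adjusted p of 7.3e-27; without that ant the colony 3 slope was 1.06 ± 0.17 (SE) and the edgeR adjusted p 0.0369. For evm.model.ctg89.12 the interaction had an edgeR adjusted p of 0.052, and of 0.0429 without the colony 4 ant at 74.9 CPM. With age given its own slope in each colony, 399 genes were called.

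**Figure D3:**
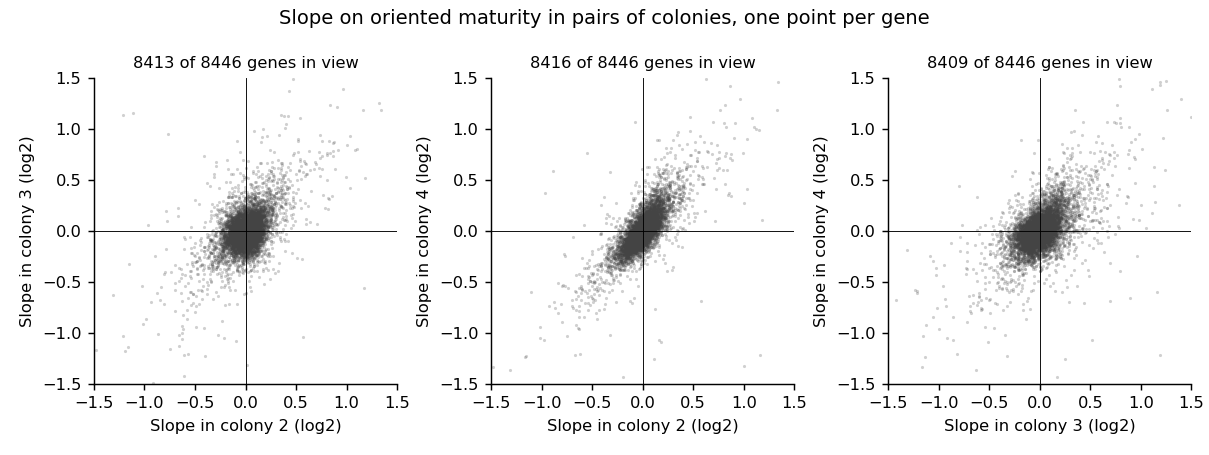
Slope on oriented maturity (log2 change from 0 to 1) in a pair of colonies fitted alone, with a point for each of the genes with an average log2 CPM of at least 2. Of 8446 such genes, 8413, 8416 and 8409 lie within the axis limits of 1.5 log2, and the cloud is narrowest for colonies 2 and 4.

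Age and maturity were tied within colonies, and nearly as many genes changed with age as with maturity. Age alone called 4458 genes, 2271 rising and 2187 falling, with a median absolute slope of 0.0619 log2 per 12 months. Of these, 3991 were also called for maturity alone, each in the same direction. With both in the model, maturity called 1941 genes, 1028 rising and 913 falling, and age called 833, 475 rising and 358 falling. Both were called in 300 genes, 256 of them in the same direction and 44 in opposite directions; both slopes come from the same ants, so these calls are not independent. The order of the 2 counts turned in other settings: with 3 residual components of the model without the tested terms added, maturity called 2956 genes and age 3351, and with foraging and brood care also in the model, maturity called 87 and age 760. Those components leave out both terms, so they can hold the tested signal itself. With 3 components of the full model's residuals, chosen after seeing the data, maturity called 3130 genes and age 1776. Without colonies 2, 3 and 4 in turn, the joint model called 1292, 2184 and 924 genes for maturity and 593, 646 and 374 for age, and with log2 library size added it called 2321 for maturity and 1455 for age.

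The joint model gave each of the 4 named gene models a slope on maturity and a slope on age. In the joint model evm.model.ctg89.12 rose with maturity by 0.98 ± 0.11 log2 and with age by 0.87 ± 0.05 log2 per 12 months (SE; edgeR adjusted p of 4.31e-14 and 2.87e-38). The fall of evm.model.ctg75.11 stayed with maturity, at -3.55 ± 0.46 log2 (SE; edgeR adjusted p = 2.61e-11), and its slope on age was 0.00 ± 0.19 (edgeR adjusted p = 0.999). The gene model evm.model.ctg53.29 fell with both, with slopes of -8.01 ± 0.81 log2 on maturity and -1.98 ± 0.37 log2 on age (SE; edgeR adjusted p of 2.29e-17 and 2.22e-05). For evm.model.ctg8.121, the slope on maturity with age in the model was -0.27 ± 0.37 and that on age 1.48 ± 0.15 log2 (SE; edgeR adjusted p of 0.707 and 5.84e-17). Without the ant at 1417 CPM, which was 45 months old, they were 0.50 ± 0.18 and 0.06 ± 0.09 (SE; edgeR adjusted p of 0.0371 and 0.785).

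Expression also changed with what the ants did, and less so once maturity was in the model. The nurse-forage ratio alone called 3802 genes, 1992 rising and 1810 falling with foraging. Brood care alone called 4699 genes, 2291 higher and 2408 lower in ants that tended brood more. With maturity in the model, foraging called 413 genes (181 rising, 232 falling) and brood care 707 (342 higher, 365 lower). The split for brood care moved with the method, to 271 higher and 420 lower with DESeq2's size factors and to 364 higher and 284 lower with limma-voom. Maturity called 2825 genes with foraging in the model and 2072 with brood care in the model. The gene model evm.model.ctg89.12 rose with foraging alone by 1.39 ± 0.19 log2 and had a slope of -1.02 ± 0.21 on foraging once maturity was in the model (SE; edgeR adjusted p of 9.28e-11 and 0.000314). With maturity as a linear term in the model, evm.model.ctg53.29 rose with brood care by 0.80 ± 0.14 log2 per doubling of the tally plus 1 (SE; edgeR adjusted p = 1.16e-05). This slope was not fitted without the ant at 147.7 CPM. With 3 residual components of the model without the tested terms added (both terms of a joint model), brood care called 1002 genes alone. With maturity in the model brood care then called 75 higher and 27 lower, and foraging called 775. Maturity then called 3315 genes with brood care in the model. With components of the full model, brood care called 2592 genes and foraging 979 with maturity in the model. With runs of 10 ants of consecutive numbers in a colony as blocks, brood care called 391 with maturity in the model.

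Of the other labels, queen attending and body length were tied to the most genes. Queen attending, which fell with maturity (rank correlation within colonies of -0.76), called 4127 genes alone and 1412 with maturity in the model, 703 higher and 709 lower. Body length called 3031 genes alone and 3168 with maturity in the model, 1636 higher and 1532 lower in longer ants, at a rank correlation with maturity of -0.13. Nest cleaning called 693 genes alone and 977 with maturity. Guarding called 1116 alone and 62 with maturity, foraging-side trophallaxis (mouth-to-mouth food sharing) 2899 and 292, and foraging-side cleaning 1567 and 15. Nest trophallaxis called 68 and 13 genes and nest grooming 234 and 13. With limma-voom, nest grooming called 0 genes with maturity in the model (557 at an unadjusted p under 0.05, against 580 with edgeR) and foraging-side trophallaxis 193. Body length added 1.89% of the variance within colonies to maturity, queen attending 1.01%, nest cleaning 0.899%, age 0.849%, brood care 0.848% and foraging 0.623%.

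**Figure D4:**
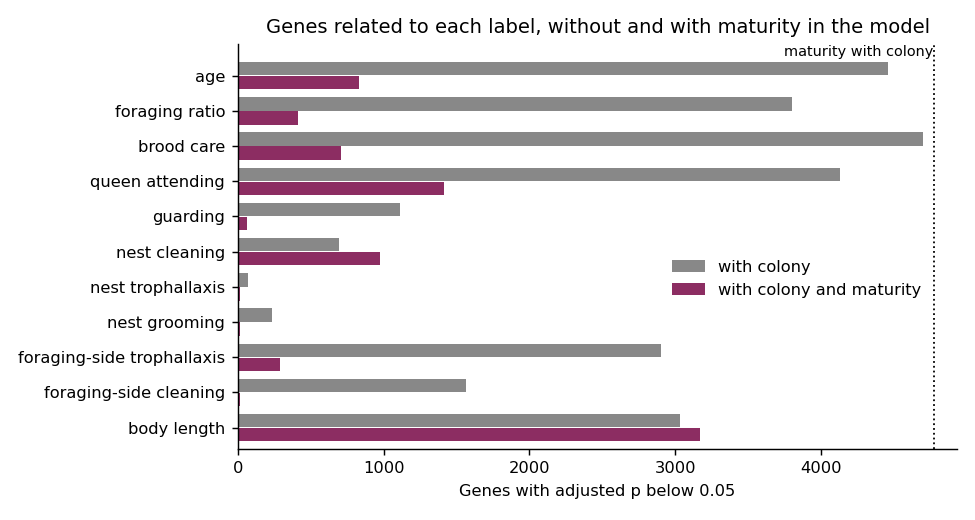
Number of genes with an adjusted p below 0.05 for each label, with colony in the model (grey) and with colony and maturity in the model (purple), over 289 ants. The dotted line marks the 4770 genes called for maturity with colony, and body length and nest cleaning are the labels here whose counts did not fall with maturity in the model.

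The colonies differed from each other in more genes than any label changed, except for colonies 2 and 3. With maturity and age in the model, 7036 genes differed between colonies 2 and 4, 3944 higher in colony 4 and 3092 higher in colony 2, or 3565 and 3326 with DESeq2's size factors. Between colonies 3 and 4, 6653 genes differed, 3908 higher in colony 4 and 2745 higher in colony 3, or 3561 and 2989 with those factors. Between colonies 2 and 3, 4389 genes differed, 2240 higher in colony 3 and 2149 higher in colony 2, an order that turned with those factors (2137 and 2243) and with no filter on low counts (2486 and 2629). The larger differences leaned to the other side: of the 338, 305 and 210 called genes that differed by more than 1 log2, 26.6% and 38.4% were higher in colony 4 than in colonies 2 and 3, and 32.9% higher in colony 3 than in colony 2. In the same order, the median absolute differences of called genes were 0.185, 0.159 and 0.147 log2. The first principal component of expression held 13.5% of the variance, and colony explained 59.7% of it. The labels give no batch, so a batch of sampling or sequencing that follows colony cannot be told apart from it.

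Library depth moved with expression within colonies, and took more of its variance than any label tested. Log2 library size took 10.9% of the variance within colonies and 43.2% of the first principal component there. Mean library totals were 37.9 ± 8.20 M reads (SD, n = 162) at the low end of maturity and 39.5 ± 8.81 M (SD, n = 87) at the high end. Within colonies 2, 3 and 4, Pearson's r between log2 library size and maturity was 0.028, 0.046 and 0.13 and Spearman's rho 0.085, -0.056 and 0.13, with no adjusted permutation p below 0.51. Without the 2 ants farthest in maturity, r was 0.016, 0.046 and 0.17.

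Depth also went together in ants with consecutive numbers, within colonies 3 and 4. The ants of each colony were taken in the order of their numbers, in 27 runs of 10 ants or, at the end of a colony, up to 18. Runs held 58.4% of the variance of log2 library size in colony 4 and 27.7% in colony 3, where permuted ants gave 8.76% and 8.23% on average (adjusted permutation p of 6e-05 and 0.00072), and 14.2% in colony 2 (8.11%, adjusted permutation p of 0.14). The median library total of a run went from 29.5 to 62 M reads in colony 4, from 29.8 to 44.1 M in colony 3 and from 33.6 to 45.8 M in colony 2. The first principal component within colonies followed the runs in colony 4, at 58.1% of its variance (adjusted permutation p = 6e-05), and the test was not passed in colonies 2 and 3 (6.92% and 12.4%, adjusted permutation p of 0.56 and 0.17). In colony 3 maturity and age followed them too, at 30.6% and 28.9% (adjusted permutation p of 0.00024 and 0.00051), over 12 such relations tested. With the runs as blocks, maturity alone called 4953 genes, 4303 of them among the 4770, maturity given age 2176, age given maturity 828 and the interaction of maturity and colony 1753. The slope of evm.model.ctg8.121 on maturity was then 0.92 ± 0.19 log2 (SE; edgeR adjusted p = 1.28e-05).

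Brain expression predicted the maturity of ants left out of the fit. The R-squared against the colony mean was 0.829 for maturity, 0.767 for age, 0.693 for the nurse-forage ratio and 0.648 for brood care (n = 289). Each lay above all 99 permutations, whose highest R-squared was 0.0345, with a permutation p of 0.01, the smallest they can give. The R-squared for maturity was 0.811, 0.845 and 0.833 in colonies 2, 3 and 4. Trained on 2 colonies and applied to the third, the prediction of maturity reached 0.732 in colony 2, 0.811 in colony 3 and 0.800 in colony 4. Expression and maturity of the third colony were centred on its own means, so only differences between its ants were predicted. In units of the variance of each label within colonies, the mean squared error was 0.172 for maturity, 0.242 for age, 0.328 for foraging and 0.366 for brood care. The mean error for maturity was below that for foraging and brood care (adjusted permutation p of 1.5e-05 for each), although the error for maturity was the larger in 152 of 289 ants against foraging; against brood care it was the smaller in 173. Against age the difference did not pass the test (permutation p = 0.0944), and the error for maturity was the larger in 154 of 289 ants.

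**Figure D5:**
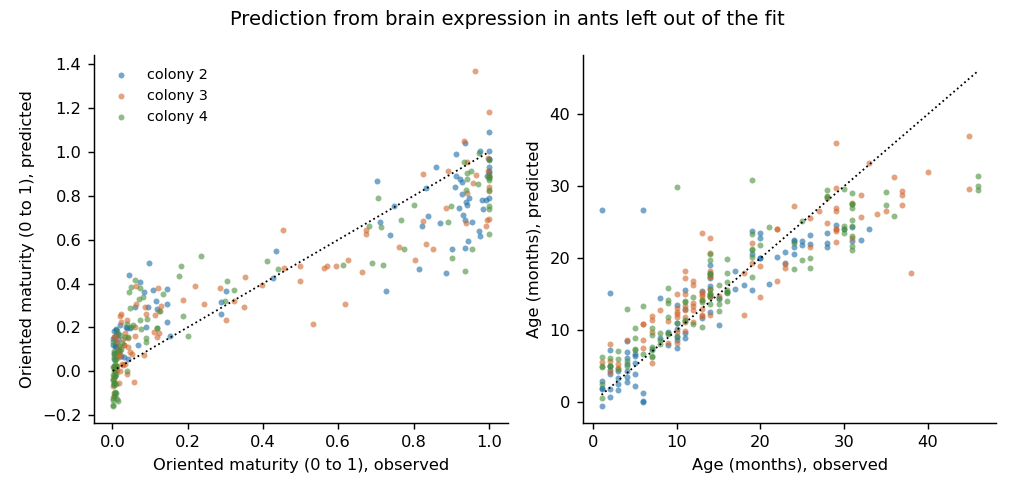
Predicted against observed oriented maturity (0 to 1) and age (months) in ants left out of the fit, with a point for each of 289 ants coloured by colony and a dotted line where both are equal. The R-squared was 0.829 for maturity and 0.767 for age, and single ants lie far from the line for age.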

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

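The tests of age and of runs of consecutive ants on the slopes that differ between colonies, that of the reversed maturity axis, the values without single ants and the counts over other splits were chosen after the results were seen. The model with library size was set before any expression value was examined. The slopes of 1696 genes on maturity differed between colonies by the interaction test. Among the named gene models, evm.model.ctg75.11 had slopes that differed (edgeR adjusted p = 0.000222, and 0.0018 without the ant with its highest value). Its medians from the low to the high end fell alike: 23 to 4.78 CPM in colony 2, 21.7 to 3.62 in colony 3 and 24.2 to 4.59 in colony 4. Its slopes were not fitted without a high-end ant of colony 2 at 242.2 CPM, so single ants may account for the difference. The interaction for evm.model.ctg8.121 (edgeR adjusted p = 7.3e-27) rested largely on 1 ant of colony 3, and its edgeR adjusted p was 0.0369 without that ant, where the colony 3 slope was 1.06 ± 0.17 log2 (SE) in place of 6.05 ± 0.50.

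Colony 3 stood furthest from the others, with a median slope difference from colony 2 of 0.208 log2 (median SE 0.0696) in the 1696 genes, against 0.0898 (0.0675) for colony 4. With log2 library size in the model 2011 genes differed. That model held a single slope on depth for all colonies, and the sizes of the differences were not taken. A link of library depth with maturity therefore stays open. For colony 3, processing in groups of consecutive ants is argued against as the whole cause, as far as it shifts the mean of a run. With runs of such ants as blocks 1753 genes differed, and the median difference of colony 3 from colony 2 was 0.217 log2 (median SE 0.0751). A different tie of age to maturity in each colony is argued against as the whole cause for colony 3, within these genes. With age by colony in the model the median difference of colony 3 from colony 2 was 0.232 log2. The median SE was 0.107 against 0.0696 before, so the fall to 399 calls came with wider errors and no smaller median difference. Wider errors can themselves raise a median absolute difference. The 1696 genes were picked by the interaction in the same ants, which builds large differences into the set. Both arguments, on runs and on age, therefore hold only as far as these calls are not chance. With residuals permuted within colony, 2 of 100 splits, the real one included, gave as many genes. The real split called 1561 with limma and the highest other 2525, so chance is not excluded for this count. These splits exchanged ants freely within a colony, although maturity followed runs of consecutive ants in colony 3. For colony 4 neither age nor such groups can be told apart from a difference between colonies, since its median differences from colony 2, 0.103 log2 with age by colony (median SE 0.0948) and 0.0939 with the runs as blocks (0.0685), lay within 2 median SEs, as they did before; a difference between the colonies themselves stays open, as does a batch that follows colony, which cannot be told apart from it.

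The deposited maturity of colony 4 ran opposite to that of colonies 2 and 3 against age, brood care and foraging. Expression in colony 4 itself did not run opposite: across genes, its slopes on age, which do not use maturity, correlated with those of the other colonies, with a lowest Spearman's rho of 0.486. Its slopes on maturity as deposited correlated negatively with theirs, with rho of -0.467 for colony 3 and -0.665 for colony 2. These are the correlations of the oriented slopes with the sign turned by construction, so they are not separate support. The labels and the slopes on age go with an axis deposited in the reverse direction for colony 4. Whether the score was made or recorded differently in that colony was not tested.

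The size of the rise of evm.model.ctg8.121 rested largely on 1 ant of colony 3 at 1417 CPM, 1070 times the median of its colony, and the slope was 0.60 ± 0.12 log2 (SE) without it. In that ant 21 of 8446 genes, this gene model included, stood at 10 or more times their colony median (medians under 0.1 CPM set to 0.1), against a median of 3 over the ants and a 75th percentile of 5, and 99.3% of ants had as many or fewer. RNA of another tissue in that library is a candidate explanation by a bound set before the count was seen, which was 20 genes. The identifiers carry no names, so no tissue could be named and a state of that ant's brain stays open. No biological explanation was tested for this ant.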

How the results depend on the processing

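The alternatives with 3 components of the full model's residuals, age by colony, library size with body length, runs of consecutive ants as blocks and single ants left out were chosen after seeing the data. Of 156 values of counts and predictions under an alternative, 43 moved past the set bounds (1.5 times for a count), and 29 of 30 slopes of named gene models on maturity kept their direction and call. Among those kept, evm.model.ctg8.121 was at 0.37 without colony 3 (edgeR adjusted p = 0.0478), 0.60 without its highest ant and 0.92 with the runs as blocks, and evm.model.ctg53.29 gave no value without colony 2 or colony 4, where it did not pass the filter on low counts. The exception was evm.model.ctg8.121, at -0.27 with age in the model against 2.89. Without its highest ant that joint slope was 0.50 and was called. Except for maturity as deposited, and unless stated, the cause of the moves below was not tested.

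With maturity as deposited, maturity alone called 553 genes (4770 as oriented), maturity given age 174 (1941), age given maturity 4377 (833) and the interaction with colony 5418 (1696); the slopes of colony 4 then oppose the others by construction. With 3 components of the model without the tested terms, maturity given age called 2956, age given maturity 3351 and maturity given brood care 3315 (2072). Brood care alone then called 1002 (4699), brood care given maturity about 1.0e+02, 75 higher and 27 lower (707), and foraging given maturity 775 (413). For maturity alone that setting called 3819 genes, 1917 of them among the 4770. With components of the full model, maturity given age called 3130, age given maturity 1776, maturity given brood care 3348, brood care given maturity 2592, foraging given maturity 979 and the interaction 3806. Maturity given age called 87 with foraging and brood care added, 3024 with ranked maturity, and 1292 and 924 without colonies 2 and 4, against 2184 without colony 3. Age given maturity called 374 without colony 4 and 1455 with library size. Foraging given maturity called 693 with no filter, brood care given maturity 391 with runs of consecutive ants as blocks, and the interaction 399 with age by colony. With limma-voom, foraging-side trophallaxis given maturity called 193 (292) and nest grooming given maturity 0 (13 with edgeR, which had 580 genes at an unadjusted p under 0.05; limma-voom had 557).

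The R-squared of maturity, age, foraging and brood care was 0.625, 0.557, 0.459 and 0.483 with a penalty 10 times larger, 0.852, 0.808, 0.754 and 0.675 with one 10 times smaller, 0.780, 0.701, 0.641 and 0.592 when trained on 2 colonies, and 0.838, 0.785, 0.595 and 0.634 for ranks. With training on 2 colonies, the third was centred on its own means.

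The depth minimum of 3 M reads left out no library and gave no value, and the gene list alternatives were not run because the identifiers carry no names. No paired analysis was possible because the numbers only name ants within a colony. At these depths, simulated slopes of 0.25 log2 on maturity alone were recovered in 82.1% of genes, so smaller slopes can be missed. With age in the model 71.6% of them were recovered, and 85.1% of slopes of 0.5 log2, so slopes of these sizes can be missed too.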

Other observations

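The tests over other splits of the ants were chosen after the results were seen; the tests of graded expression, neighbouring gene models and library size in the body length model were set before their values were seen.

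Longer ants differed from shorter ants at the same maturity in 3168 genes, with slopes that were partly shared by the colonies. Fitted alone, colonies 2, 3 and 4 called 2276, 383 and 1491 genes for body length with maturity in the model. Across the 10457 genes, Spearman's rho of these slopes was 0.585 between colonies 2 and 3, 0.421 between 2 and 4 and 0.395 between 3 and 4. Body length ran from 7.45 to 12.8, in a unit the labels do not give, with a mean of 9.33 ± 0.98 (SD, n = 289). With log2 library size also in the model, 3178 genes were called.

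In 7 ants the age predicted from brain expression missed the recorded age by more than 15 months, where the median absolute miss was 2.45 months; these ants were picked after their values were seen. Among them were 3 young ants of high maturity. An ant of colony 2 aged 1 month, with an oriented maturity of 0.859, had a predicted age of 26.7 months, another of colony 2 aged 6 months with a maturity of 0.912 had 26.8 months, and an ant of colony 4 aged 10 months with a maturity of 0.939 had 29.9 months. The brood care tally of each of these 3 was 0. Conversely, an ant of colony 3 aged 38 months with a maturity of 0.13 had a predicted age of 17.9 months and a predicted maturity of 0.296. The remaining 3 ants were 45 or 46 months old and were predicted at 29.5 to 30.0 months. The 2 young ants of colony 2 had consecutive numbers (50 and 51), and their recorded ages were not checked. Other young ants of high maturity were predicted younger. In colony 2, an ant aged 8 months with a maturity of 0.814 had 8.90 months, and another aged 4 months with 0.887 had 8.53 months. In colony 4, an ant aged 4 months with a maturity of 0.937 had 12.9 months.

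One hypothesis was that brain expression differs only between a low and a high state. In the 40 ants with oriented maturity from 0.25 to 0.75, predicted and observed maturity, centred within colony, had Pearson's r of 0.677 (permutation p = 4e-05, adjusted p = 4e-05) and Spearman's rho of 0.671 (permutation p = 3e-05), and r was 0.629 without the 2 farthest ants. Inside the low end r was 0.697 (n = 162) and inside the high end 0.454 (n = 87), with adjusted permutation p of 3e-05 for each. A mix of 2 states whose shares change with maturity would also give such correlations, so they do not decide the question. Predicted maturity was 0.477 ± 0.154 (SD) in these 40 ants, 0.134 ± 0.151 at the low end and 0.798 ± 0.169 at the high end. Whether single ants between the ends stood in 1 of 2 states was not tested. Age was not held fixed, so a graded change in the brain along maturity cannot be told apart here from a change along age.

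Gene models with consecutive numbers on a contig may share their slopes on maturity. Spearman's rho of the slopes was 0.153 over 8994 pairs of consecutive models, above the highest of 1000 shuffles (0.0349), 0.0638 at a distance of 2, and -0.00836 at a distance of 10. Of 2036 consecutive pairs with both models called, 1211 changed in the same direction. Genes split between models, overlapping models counted together and neighbours regulated together stay open, since no annotation was used here.

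In the 10 ants without labels, evm.model.ctg89.12 ran from 4.09 to 36.7 CPM (median 13.5), evm.model.ctg75.11 from 3.35 to 54.0 CPM (median 17.3), evm.model.ctg53.29 from 0 to 13.7 CPM (median 0.175) and evm.model.ctg8.121 from 0.758 to 1.57 CPM (median 1.18).

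Chance assignment of the labels was tested over 100 splits for the results named here, with calls counted by limma. The other labels and the fits within single colonies were not permuted. The splits exchanged ants freely and did not keep runs of consecutive ants together. They argue against chance only where no other split reached the real count, and only as far as ants can be exchanged. Only the real split, 1 of 100, gave as many genes for maturity alone (4767, highest other 180), age alone (4456, 1), foraging alone (3771, 1209), brood care alone (4702, 1), maturity given age (1898, 2), foraging given maturity (384, 1), maturity given foraging (2811, 1), maturity given brood care (2042, 11), and colonies 2 and 3 (4045, 2), 2 and 4 (7154, 1) and 3 and 4 (6675, 2914). For age given maturity 2 of 100 splits gave as many (808, highest other 1668), as they did for brood care given maturity (638, 909). Chance is therefore not excluded for these counts. What raised the counts of such permuted splits was not tested, since no split was repeated with runs, library size or components in the model. The calls for age and brood care with maturity in the model, and for slopes that differ between colonies, stand closest to these permuted counts.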
